A study of Mus musculus with 5 samples.

How the data were processed

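RNA-seq had been made from haematopoietic stem and progenitor cells (HSPCs) of mice, sorted as lineage-negative, KIT-positive, SCA1-positive and CD135-negative cells, per the labels. The 5 libraries fell into 2 groups named in the labels: 2 libraries from mice with Cux1 knocked down (Cux1-low) and 3 from mice with Cux1 knocked down and an NrasG12D allele (Cux1-low;NrasG12D, called the NrasG12D libraries from here on). Per the labels' protocols, the mice of both groups had received pI:C, a synthetic double-stranded RNA that induces interferon, and doxycycline for 4 weeks. RNA was isolated with Trizol, and polyA RNA libraries were made with an Illumina TruSeq v2 kit. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples, part of which may be technical. Libraries with normal Cux1, or with NrasG12D alone, were not analysed here.

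The submitters' processing notes name TopHat, HTSeq and edgeR, without versions or roles, and the builds hg19 and mm10, of which mm10 is the mouse build. The authors' deposited table lists 11352 genes, each with a value above 1 in at least 3 of the 5 libraries. The list can therefore hold genes above 1 only in the NrasG12D libraries, but none above 1 only in the Cux1-low libraries. Counts and rankings of higher and lower genes thus do not cover both directions alike. The table gives 1 value per library that is headed CPM, a read count scaled to library size, per the file headers. These deposited signal values are not plain CPM, because the columns sum to 971746 to 1026780, so each library total had been multiplied by a composition factor (0.974 to 1.03). They are called normalized CPM below. The deposited table also holds the authors' own comparison: a log2 fold change, a mean log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value per gene. A positive log2 fold change there means a higher value in NrasG12D, which was checked against the library columns. Whether counting used strand is not given in the sources used here. Neither reads of overlapping and antisense genes nor those of near-identical gene copies could therefore be assigned with certainty.

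Every value was a whole multiple, within a tolerance of 0.001 of a step, of 1 smallest step per library. That step, the value of 1 read, was 0.0481 to 0.0608, which gives 16489711 to 20262498 reads per library over the listed genes. Too few values were low for the unit check used here to accept recovered reads, so no test of the groups on read counts was run, and the reads served only to compare libraries with one another and to judge low levels. The planned fallback for normalized values was used: limma with a trended variance (limma 3.58.1 in R 4.3.3) on log2(normalized CPM + 1), 3 NrasG12D against 2 Cux1-low libraries, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes needed a value of at least 1 in at least 2 libraries, which removed 0 of 11352. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and their standard errors (SE) come from the same fit. Ratios of group means are on the normalized CPM scale, and values after ± are SDs over the 2 Cux1-low or the 3 NrasG12D libraries.

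Before the data were examined, 33 gene lists with 624 genes had been written, covering pathways downstream of RAS, cell cycle, stress, metabolism and the cell types that such a sort could hold. Of these genes, 513 were measured. The 30 lists with at least 5 measured genes, other than the sort gate and sex-linked genes, were tested with limma's camera (2-sided, preset inter-gene correlation of 0.01, adjusted over the 30 lists). The same test with an estimated correlation, and fry, were alternatives. The rule for named genes had also been fixed: Cux1 and Nras, then the 12 genes with the largest change in each direction. Those needed an adjusted p under 0.05, a mean log2 value of at least 2 and groups that did not overlap. Gene models without a descriptive symbol, small RNAs, pseudogenes and sex-linked genes were counted, not named. For each list, up to 4 members past the threshold were named, or 2 with the smallest p where fewer than 2 passed. Of the genes this rule selects, 3 are counted but not reported by name here. Genes outside this rule are marked as chosen after their values were seen.

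Coordinates are those of GENCODE release M21 on mm10. Of the listed symbols, 10941 matched directly and 354 through an older symbol, and 57 did not match. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The position of a library between the groups was expressed, per gene, as a relative position: 0 at the Cux1-low mean and 1 at the mean of NrasG12D libraries 1 and 2. For lists, the median was taken over members that differed at least 2-fold between those means. Positions were computed on the normalized CPM scale, not in log2. A value midway in log2 therefore lies nearer 0 for higher genes and nearer 1 for lower genes.

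The limma fit was tested on simulated data with 11352 genes, 2 against 3 libraries and 200 changed genes. With the residual spread of the data, 52% of 2-fold and 94% of 4-fold changes were called, and 9 unchanged genes were called. With the residual spread of the data without NrasG12D library 3, these shares were 79% and 98%, with 6 unchanged genes called. The simulated noise was independent between genes, whereas NrasG12D library 3 was displaced over many genes together. The simulated shares and false calls may therefore not hold for the data. Alternatives were pseudocounts of 0.1 and 0.5, no filter, filters of 5 CPM and of 50 reads, other scalings, a replicate block, each library left out, and other thresholds. Robust limma, library weights and the authors' deposited comparison were added after seeing the data. Planned tests of the groups on read counts were not run.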

Results

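The transcriptomes of sorted mouse HSPCs were compared between 2 Cux1-low libraries and 3 Cux1-low;NrasG12D libraries. CUX1 is a homeodomain transcription factor, and NrasG12D is an oncogenic form of the small GTPase NRAS. The series title states that CUX1 deficiency and RAS signalling were studied together, and the comparison asks what the NrasG12D allele adds to HSPCs in which Cux1 is already knocked down. The Cux1-low libraries held 19822779 and 20262498 reads over the 11352 listed genes, and the NrasG12D libraries held 20019507, 17975309 and 16489711. One read corresponded to 0.0481 to 0.0608 normalized CPM, so genes below about 1 CPM rested on few reads. Chi-square tests of the reads found a difference beyond sampling noise in all pairs of libraries. This argues against repeated deposits of the same library, and does not show that they came from separate animals.

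Cux1 (chromosome 5, 136248135 to 136567490, minus strand) and Nras (chromosome 3, 103058285 to 103067914, plus strand) were read first. Cux1 was at 306 and 281 normalized CPM in the Cux1-low libraries and at 311, 279 and 307 in the NrasG12D libraries. The log2 fold change was 0.02 (SE 0.10, limma adjusted p = 0.883). Nras was at 144 and 115 against 126, 124 and 113, a log2 fold change of -0.09 (SE 0.13, limma adjusted p = 0.642). No difference in the mRNA level of either gene was detectable, and the sign of both small values depended on single libraries. Both groups carry the Cux1 knockdown, and a total mRNA level does not separate the mutant from the normal Nras allele, so these values check neither the knockdown nor the allele.

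Between the groups, 29 genes rose and 99 fell in the NrasG12D libraries (limma adjusted p under 0.05, 11352 genes tested), and 3559 had an unadjusted p under 0.05. Genes above 1 normalized CPM only in the Cux1-low libraries were not listed, so the count of falls leaves out any such genes. For all 128, every library of one group lay above every library of the other. Such separation held for 53.5% of all genes, where a random order of the 5 libraries gives 20% per gene on average. Genes share the same 5 libraries and vary together, so the distance between these shares does not measure evidence for the groups. In the authors' deposited table, 1829 genes passed the same threshold, 791 higher and 1038 lower, and these included all 128 with the same sign. NrasG12D library 3 stood apart from libraries 1 and 2. The first principal component held 73.8% of the variance and placed the Cux1-low libraries at -32.8 and -30.1, NrasG12D libraries 1 and 2 at 29.1 and 38.0, and library 3 at -4.16. Without that library, 4243 of 11352 genes passed, 2043 higher and 2200 lower, among them all 128. List counts without library 3, given below, are to be read against these shares, since many genes of any list then pass. Without NrasG12D library 2, 22 passed. Without Cux1-low library 1, Cux1-low library 2 or NrasG12D library 1, 3 passed in each case, namely Hspa1a, Hspa1b and the antisense gene Gm15915, which was chosen after its values were seen.

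**Figure D1:**
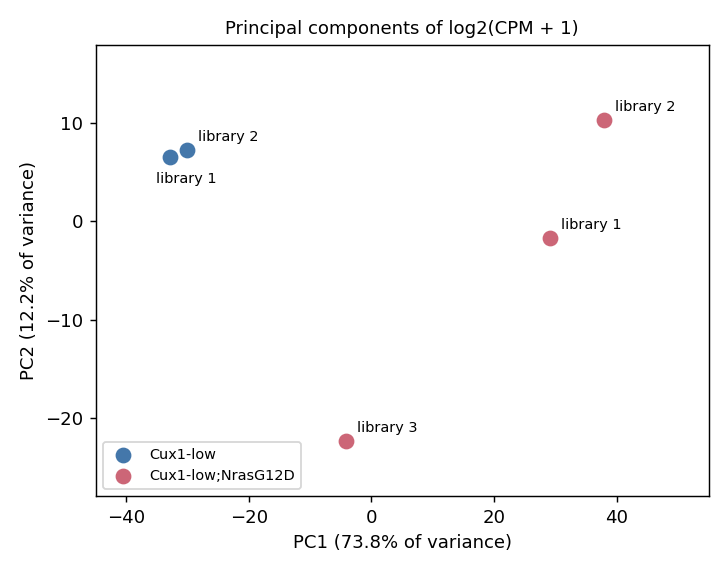
First and second principal components of log2(normalized CPM + 1), each point a library, coloured by group. NrasG12D library 3 lies at -4.16 on the first axis, between the Cux1-low libraries (-32.8 and -30.1) and NrasG12D libraries 1 and 2 (29.1 and 38.0).

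The heat shock genes Hspa1b and Hspa1a, which encode inducible HSP70 chaperones, had the largest positive log2 fold changes among the named genes on the log2(normalized CPM + 1) scale, and Slc30a10 had a larger ratio of group means (42.5-fold, against 29.6-fold for Hspa1b). Hspa1b went from 13.7 ± 2.07 (SD, n = 2) to 406 ± 121 normalized CPM (SD, n = 3), a log2 fold change of 4.75 (SE 0.25, limma adjusted p = 0.00187). Hspa1a went from 10.7 ± 2.58 to 307 ± 101, a log2 fold change of 4.69 (SE 0.27, limma adjusted p = 0.00252). These neighbours on chromosome 17 (34956436 to 34959238 and 34969190 to 34972156) are near-identical copies, so how the reads divide between them is uncertain. Slc30a10, a manganese transporter, rose from 0.268 to 11.4 normalized CPM (log2 fold change 3.18, limma adjusted p = 0.0327), and its Cux1-low level rested on few reads. Hebp1, a haem-binding protein gene, rose 9.92-fold (5.01 ± 0.339 to 49.6 ± 19.5), and Tnfrsf14, which encodes the receptor HVEM, rose 9.04-fold (4.23 ± 1.15 to 38.3 ± 13.6). In library 3, Hebp1 was at 29.3 and Tnfrsf14 at 24.97, below libraries 1 and 2. Supt16, a subunit of the FACT histone chaperone, rose from 73.8 ± 12 to 267 ± 37.4 normalized CPM (log2 fold change 1.84, limma adjusted p = 0.0113). Ntn4, which encodes a netrin, rose 5.73-fold, and its span in the genome overlaps that of the antisense gene Gm15915. Whether their exons overlap was not checked, so how reads divide between the pair is uncertain. Emp1, Lbh and Crip2 rose 3.74-fold, 3.46-fold and 2.49-fold. The inflammatory genes Cxcl2 and Tnf rose 4.76-fold and 2.68-fold, from low levels of 1.34 and 4.91 normalized CPM.

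Among the genes that fell, Fn3krp (chromosome 11, 121421401 to 121431288), a kinase that removes sugar adducts from proteins, went from 28.6 ± 1.71 to 2.73 ± 0.424 normalized CPM. Its log2 fold change was -2.99 (SE 0.19, limma adjusted p = 0.00351), and library 3 (3.22) lay near libraries 1 and 2 (2.46 and 2.51). Npdc1 fell from 17.2 ± 0.396 to 2.53 ± 0.379 (log2 fold change -2.37, limma adjusted p = 0.0113). Mmrn1, which encodes multimerin of platelets and endothelium, was the most abundant of the 12 and fell from 410 ± 0.918 to 98.3 ± 41.8 (log2 fold change -2.13, limma adjusted p = 0.0411). The receptor tyrosine kinase gene Ephb4 was 7.01-fold lower, the C-type lectin gene Clec1a 6.17-fold lower and the matrix proteoglycan gene Bgn 5.88-fold lower. Fam181b, Ndn, Abcg3, Raver2, Acot1 and Serpina3f were 7.69-fold, 6.26-fold, 5.97-fold, 5.86-fold, 5.77-fold and 5.51-fold lower. Acot1 and Serpina3f belong to families with near-identical copies, so their levels are uncertain. Fam181b, Ndn, Acot1 and Raver2 lost their call with pseudocounts of 0.1 and 0.5, filters of 5 CPM and 50 reads, and robust limma.

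**Figure D2:**
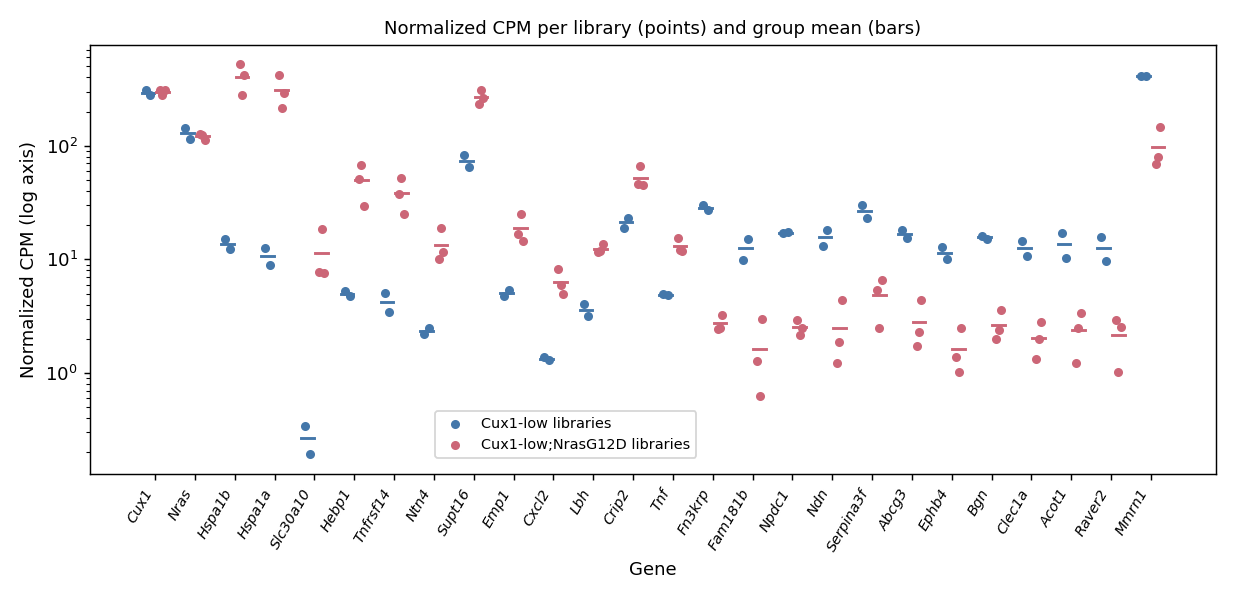
Normalized CPM (log axis) of Cux1, Nras and the 24 genes with the largest changes in each library. Points are libraries and bars are group means. Cux1 and Nras overlap between groups, and the other genes do not.

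Genes used as markers of haematopoietic stem cells (HSCs) were lower as a list. Of 23 measured, 21 had a negative sign, the median log2 fold change was -1.23, and 3 fell over all genes tested. Among these were Ndn, which encodes necdin (log2 fold change -2.33), and Gprasp2, a receptor-sorting protein gene (log2 fold change -1.80). Adjusted over the list alone, 15 fell, and without NrasG12D library 3, 20 fell and 1 rose over all genes. The list passed camera (adjusted p = 1.12e-06, 30 lists) but not with an estimated correlation (adjusted p = 0.565). Megakaryocyte and platelet genes were lower as a list too (17 measured, 15 with a negative sign, median -0.46, camera adjusted p = 0.00745, and adjusted p = 0.569 with an estimated correlation). None passed over all genes, 7 fell and 1 rose adjusted over the list alone, and without NrasG12D library 3, 10 fell and 1 rose over all genes. Rab27b was at 76.6 ± 8.34 against 36.0 ± 8.13 normalized CPM and Vwf at 71.4 ± 16.4 against 39.4 ± 2.43. Cytokine receptor genes also passed (18 measured, median -0.47, camera adjusted p = 0.0116, and adjusted p = 0.565 with an estimated correlation). Il1r1, the interleukin-1 receptor gene, fell (log2 fold change -1.05), adjusted over the list alone 7 fell and 1 rose, and without NrasG12D library 3, 10 fell and 2 rose over all genes. Kit, whose product was used for the sort, was at 1366 ± 10.1 against 621 ± 175 normalized CPM (log2 fold change -1.17, limma adjusted p = 0.0538). The relative position of library 3 had medians of 0.572, 0.560 and 0.536 over the members of these 3 lists.

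Genes of proliferation and biosynthesis were higher as lists, while none of their members passed over all genes. Without NrasG12D library 3, 17 S phase, 23 G2/M, 19 ribosomal protein, 11 MYC and ribosome biogenesis, 24 oxidative phosphorylation, 3 cholesterol synthesis and 7 DNA repair genes rose over all genes, and 1 ribosomal protein and 1 cholesterol synthesis gene fell. In that fit 2043 of all 11352 genes rose and 2200 fell, and the 3 of 21 cholesterol synthesis genes lay below that share of rises. All 22 S phase genes and all 24 G2/M genes had a positive sign (medians 0.46 and 0.52, camera adjusted p = 5.54e-07 and 1.06e-06). With an estimated correlation these gave adjusted p = 0.565 and adjusted p = 0.568. The S phase regulator E2f1 was at 71.7 ± 8.83 against 113 ± 6.89 normalized CPM and the helicase subunit Mcm7 at 380 ± 21.2 against 518 ± 51.7. The proliferation marker Mki67 was at 253 ± 7.90 against 430 ± 86.9 and Cdk1 at 170 ± 7.0 against 267 ± 48.2. Adjusted over the list alone, 11 S phase and 5 G2/M genes rose. Of 30 ribosomal protein genes, 29 had a positive sign (median 0.40, camera adjusted p = 1.61e-07, and adjusted p = 0.565 with an estimated correlation), and 15 rose adjusted over the list alone. Rpl8 was at 558 ± 2.38 against 803 ± 61.2 and Rpl14 at 133 ± 0.0649 against 186 ± 11.8. All 21 MYC and ribosome biogenesis genes had a positive sign (median 0.31, camera adjusted p = 2.26e-06, and adjusted p = 0.565 with an estimated correlation), and 11 rose adjusted over the list alone. Nop58 was at 274 ± 12.7 against 386 ± 5.88 and Npm1 at 134 ± 7.53 against 191 ± 6.22. Oxidative phosphorylation genes gave 24 of 25 positive signs (median 0.41, camera adjusted p = 5.54e-07, and adjusted p = 0.565 with an estimated correlation), and 15 rose adjusted over the list alone. Cox5a was at 119 ± 1.77 against 186 ± 19.8 and Cyc1 at 304 ± 11.8 against 459 ± 67.2. Cholesterol synthesis genes (19 of 21 positive, median 0.33, camera adjusted p = 0.000381) gave adjusted p = 0.565 with an estimated correlation. Their members Fdps and Hsd17b7 had log2 fold changes of 0.87 and 0.73, and 1 gene rose adjusted over the list alone. DNA repair genes (19 of 21 positive, median 0.23, camera adjusted p = 0.00745) gave adjusted p = 0.578 with an estimated correlation. Chek1 and Rpa2 had log2 fold changes of 0.46 and 0.36, and 0 passed adjusted over the list alone.

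**Figure D3:**
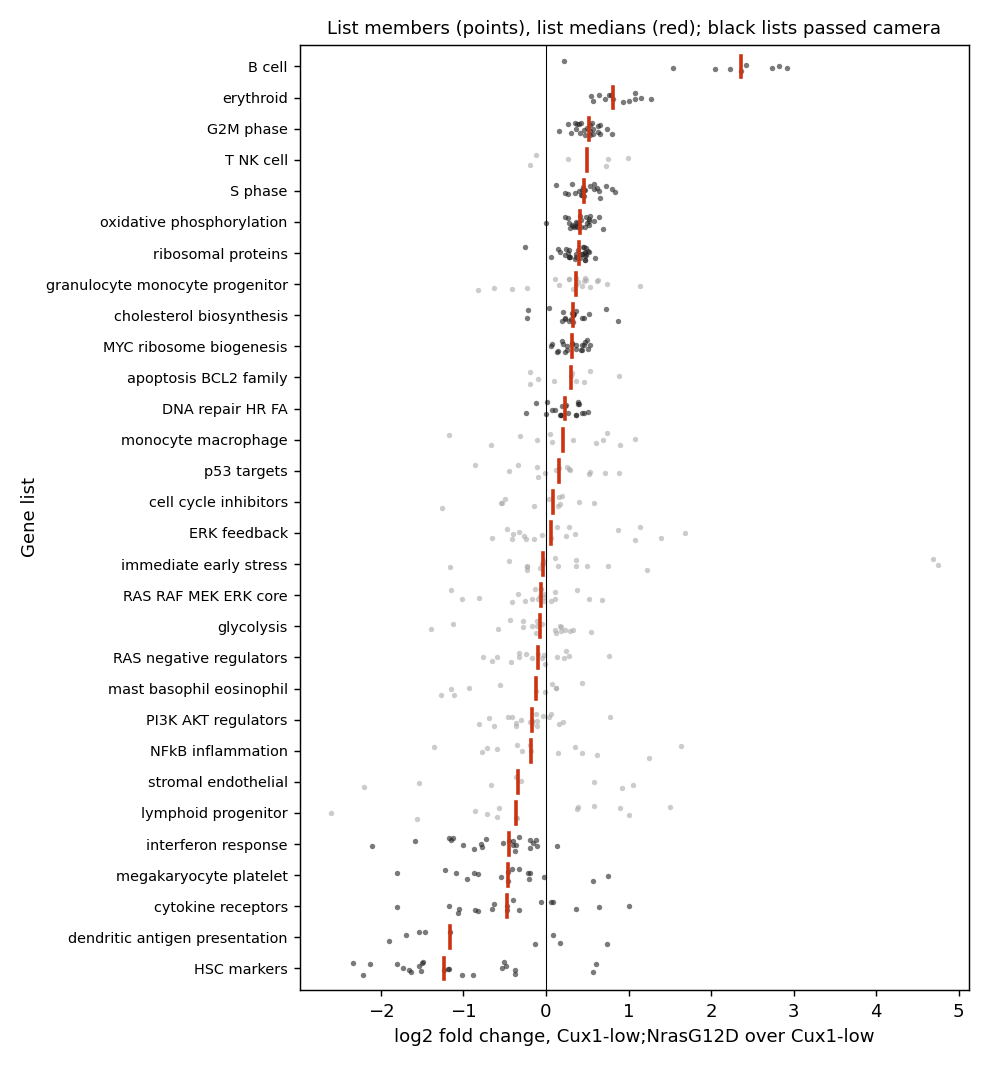
Log2 fold changes of the measured members of the 30 tested lists (points) with the list median (red line). Lists in black passed camera with the preset correlation, 9 higher and 5 lower, and those in grey did not. With an estimated correlation 0 lists passed. HSC markers have a median of -1.23 and B cell genes one of 2.37.

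Interferon response genes were lower as a list in the NrasG12D libraries (23 measured, 22 with a negative sign, median log2 fold change -0.44, camera adjusted p = 5.54e-07, and adjusted p = 0.565 with an estimated correlation). Over all genes, 2 fell and 21 did not pass. Oasl2, an interferon-induced gene, fell from 27.1 ± 1.38 to 8.41 ± 1.61 normalized CPM (log2 fold change -1.59, limma adjusted p = 0.0327), 10 genes fell adjusted over the list alone, and without NrasG12D library 3, 11 fell over all genes. The list also passed fry (adjusted p = 0.0129). Library 3 lay near libraries 1 and 2 for these genes (median relative position 0.858). Antigen presentation genes of dendritic cells were lower as a list (9 measured, 6 with a negative sign, median -1.16, camera adjusted p = 0.0215, and adjusted p = 0.565 with an estimated correlation). The MHC class II gene H2-Aa fell from 133 ± 44.2 to 40.3 ± 11.7 (limma adjusted p = 0.0478), its partner Cd74 was at 282 ± 80.3 against 96.8 ± 30.4, and 5 fell adjusted over the list alone. Without NrasG12D library 3, 5 fell and 1 rose over all genes, but this list was no longer called (adjusted p = 0.293, in a range of 0.00166 to 0.565 over 13 alternatives).

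Lists of RAS signalling genes did not pass camera. Of 19 targets and feedback regulators of ERK, Emp1 rose and 18 did not pass (median 0.06, camera adjusted p = 0.282, and 3 rose adjusted over the list alone). The feedback inhibitor gene Spry4 was at 2.19 ± 0.509 against 7.53 ± 2.25 normalized CPM (limma adjusted p = 0.0579). Without NrasG12D library 2 this list was called higher, while without NrasG12D library 3 camera's direction was lower (adjusted p = 0.984), and 3 genes rose and 5 fell over all genes. RAS, RAF, MEK and ERK genes (21 measured, median -0.06, camera adjusted p = 0.414) had 0 members past the threshold over all genes, and 2 rose and 3 fell adjusted over the list alone. This list passed fry, which does not compare it with other genes (adjusted p = 0.0389). Rasgrp2, an exchange factor, was at 78.9 ± 10.5 against 127 ± 9.99, and Rras at 14.4 ± 0.982 against 6.69 ± 1.15. Negative regulators of RAS (17 measured, median -0.10, camera adjusted p = 0.391) included Rasa3 at 373 ± 2.33 against 223 ± 54.7 and Rasal3 at 445 ± 67.3 against 298 ± 71.8. PI3K and AKT regulators (21 measured, median -0.17, camera adjusted p = 0.0704) included Pik3cd at 245 ± 11.3 against 179 ± 14.7 and Pik3ip1 at 149 ± 8.68 against 86.3 ± 19.7. In both of these lists 0 genes passed, also adjusted over the list alone. Without NrasG12D library 3, 1 negative regulator rose and 5 fell over all genes, 7 PI3K and AKT regulators fell, and of the RAS, RAF, MEK and ERK genes 3 rose and 3 fell. Of all 11352 genes, 4243 passed in that fit, a larger share than in any of these 3 lists. Without NrasG12D library 2 the PI3K and AKT list was called lower.

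Markers of other cell types moved with the groups in part. All 13 erythroid genes had a positive sign (median 0.81, camera adjusted p = 4.09e-05, and adjusted p = 0.565 with an estimated correlation), none passed over all genes, 9 rose adjusted over the list alone, and without NrasG12D library 3, 12 rose over all genes. The erythroid transcription factor gene Klf1 was at 166 and 209 normalized CPM in Cux1-low libraries and at 423, 533 and 270 in NrasG12D libraries, and Blvrb at 141 and 150 against 324, 434 and 211. The B cell list had the largest median (9 measured, 9 positive, median 2.37, camera adjusted p = 0.00885, and adjusted p = 0.601 with an estimated correlation), with 0 genes past the threshold. Vpreb3, which is expressed in precursor B cells, was at 0.931 and 1.64 normalized CPM in the Cux1-low libraries and at 20.2, 48.0 and 2.31 in the NrasG12D libraries. For the genes of this list, library 3 lay near the Cux1-low level on the normalized CPM scale (median relative position 0.00328). Its Vpreb3 value was still above both Cux1-low libraries. Without library 3 all 9 passed. Genes of mast cells, eosinophils and basophils did not pass as a list (11 measured, 7 with a negative sign, median -0.12, camera adjusted p = 0.0691). Its members Epx and Prg2, which encode eosinophil granule proteins, fell with log2 fold changes of -1.11 and -1.27, and 4 fell adjusted over the list alone. The lymphoid progenitor list (14 measured, camera adjusted p = 0.183, 6 lower adjusted over the list alone) held Flt3, which encodes the CD135 of the sort, at 357 ± 44.3 against 197 ± 32.2, and Jchain at 223 ± 156 against 34.5 ± 18.1. Among 11 sort gate genes, 0 passed over all genes, and 2 rose and 5 fell adjusted over the list alone, with a median of -0.64 and a mean of 0.11. Without NrasG12D library 3, 4 mast cell, eosinophil and basophil genes fell over all genes. In the same fit 5 lymphoid progenitor genes rose and 6 fell, and 3 sort gate genes rose and 6 fell. In that fit 2043 of all 11352 genes rose and 2200 fell.

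The remaining cell type lists did not pass. Granulocyte and monocyte progenitor genes (21 measured, median 0.36, camera adjusted p = 0.144) held Gfi1 at 57.8 ± 10.1 against 32.6 ± 7.46 and Sirpa at 88.3 ± 7.17 against 66.2 ± 7.86, and were called higher without NrasG12D library 3 or without Cux1-low library 2. Of these 21 progenitor genes, 17 had a positive sign and 4 a negative sign, with Gfi1 and Sirpa among the 4. Monocyte and macrophage genes (12 measured, camera adjusted p = 0.412) held Itgam at 41.0 ± 14.4 against 17.5 ± 4.97 and Cd68 at 15.5 ± 3.20 against 26.5 ± 4.22. T and NK cell genes (6 measured, camera adjusted p = 0.212) held Trat1 and Ccl5 at 1.77 and 2.56 against 3.63 and 6.46. The stromal and endothelial list (8 measured, camera adjusted p = 0.255) held Bgn, which fell, and Plvap at 15.4 ± 0.370 against 30.6 ± 7.27, with 1 higher and 2 lower adjusted over the list alone. Of the mature neutrophil markers, 2 of 16 were measured, Lcn2 at 1.80 ± 0.710 against 3.16 ± 1.62 and Cxcr2 at 6.99 ± 1.35 against 8.83 ± 3.50. In the progenitor, monocyte, T and NK cell and neutrophil lists, 0 genes passed, also adjusted over the list alone. Without NrasG12D library 3, 10 progenitor genes rose and 2 fell over all genes, 5 monocyte genes rose and 1 fell, and 3 T and NK cell genes rose, while in the stromal and endothelial list 1 rose and 3 fell. That fit called 2043 of all 11352 genes higher and 2200 lower.

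Stress, inflammation and growth-control lists were mixed. Of 19 immediate early and stress genes, 3 rose, namely Hspa1b, Hspa1a and Hsp90aa1, which encodes a cytosolic HSP90 (166 ± 5.75 to 280 ± 4.56 normalized CPM, log2 fold change 0.75). The list had a median of -0.04 and a mean of 0.55 (camera adjusted p = 0.0704), and 4 rose adjusted over the list alone. Of 14 NF-kB and inflammation genes, Tnf and Cxcl2 rose, while the list gave camera adjusted p = 0.771, with 2 higher and 4 lower adjusted over the list alone. Cell cycle inhibitors (12 measured, camera adjusted p = 0.771) held Cdkn1c at 14.7 ± 0.0847 against 5.79 ± 2.17 and Ccng2 at 90.9 ± 2.69 against 62.4 ± 9.16. Their median was 0.09, their mean -0.11 and camera's direction lower, with 3 lower adjusted over the list alone. The p53 target list (15 measured, camera adjusted p = 0.212) held Trp53inp1 at 37.4 ± 3.37 against 20.4 ± 3.57 and the apoptosis gene Bax at 81.2 ± 9.12 against 118 ± 8.80, with 1 higher and 1 lower adjusted over the list alone. The BCL2 family list (10 measured, camera adjusted p = 0.127) held Bax and Pmaip1, the latter at 2.11 ± 0.199 against 4.84 ± 1.44, with 1 higher adjusted over the list alone. Of 20 glycolysis genes, Ldhb, a lactate dehydrogenase subunit, fell from 35.4 ± 6.45 to 12.9 ± 2.49 (log2 fold change -1.40), Slc2a3 was at 163 ± 18.9 against 110 ± 26.2, and the list did not pass (camera adjusted p = 0.771, 1 lower adjusted over the list alone). Of 4 measured sex-linked genes, 0 passed over all genes and 1 was lower adjusted over the list alone. Kdm5d was at 34.4 ± 0.272 against 20.9 ± 5.18 and Uty at 43.6 ± 8.05 against 33.5 ± 7.29. Without NrasG12D library 3, the counts over all genes were 5 higher and 2 lower immediate early and stress genes, 3 higher and 4 lower NF-kB and inflammation genes, 2 higher and 4 lower cell cycle inhibitors, 3 higher and 2 lower p53 targets, 3 higher and 1 lower BCL2 family genes, 5 lower glycolysis genes and 1 lower sex-linked gene. That fit called 2043 of all 11352 genes higher and 2200 lower.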

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

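Robust limma, library weights, the authors' deposited comparison and the other scalings and pseudocounts of the list test were chosen after seeing the data. The 128 changed genes (29 higher, 99 lower) were 89 and 107 with pseudocounts of 0.1 and 0.5, 102 and 113 with filters of 5 CPM and 50 reads, 179 with median-of-ratios scaling, 111 with robust limma and 108 with a fold of at least 2. Scaling to library totals gave 213 genes, 31 higher and 182 lower (14.6% higher against 22.7%), and moved the median of all genes to -0.06. Library weights gave 5070 genes (47.9% higher) and the authors' deposited comparison 1829 (43.2% higher). Adjusted p thresholds of 0.1 and 0.01 gave 1870 and 5 genes. The 5 were Gm15915, Hspa1b, Hspa1a, Fn3krp and Serpinf1, named after their values were seen. Leaving out each library gave 3 to 4243 genes, the highest without NrasG12D library 3. Where Cux1-low keeps 1 library, that library is assumed to vary like the other group. All 5 of these fits have fewer libraries, which lowers power, while the median residual SD fell from 0.170 to 0.125 without library 3. The causes of the changes in count were not tested.

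The groups share only the numbers 1 and 2, whose deviations from their group means had correlations of -0.192 and -0.00354 across genes, without a sign of pairing. The deviations of the 2 Cux1-low libraries mirror each other, and library 3 enters the NrasG12D mean. These correlations therefore cannot settle whether the numbers pair the libraries. A replicate block gives NrasG12D library 3 its own term and so leaves it out, and gave 4163 genes (1892 higher, 2271 lower, 45.4% higher) and 15 lists.

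Cux1 and Nras passed under none of these settings. Cux1 changed sign with library totals (-0.039), without Cux1-low library 2 (-0.037) and without NrasG12D library 1 (-0.0045), in a range of -0.037 to 0.087 over left-out libraries. Nras changed sign without Cux1-low library 1 (0.069), in a range of -0.25 to 0.069. Cxcr2 had a sign change, to -0.021, with the replicate block and without NrasG12D library 3, in a range of -0.021 to 0.44 over left-out libraries. The other named genes kept their sign in every fit. Without either Cux1-low library or NrasG12D library 1, 32 of the named genes lost their call in each fit, and 23 did without NrasG12D library 2. Of the named genes, 9 lost it with a pseudocount of 0.1, 5 with 0.5, 6 with the filter of 5 CPM, 4 with the filter of 50 reads and 5 with robust limma. Fam181b, Ndn, Acot1 and Raver2 did so in all 5 of these fits. The 14 lists were 0 with an estimated correlation, 4 with fry (the interferon and MYC lists, the RAS core and p53 targets), and 14 to 17 with each library left out. Lists gained a call in single fits. Immediate early and stress genes did so with library totals and without Cux1-low library 2 or NrasG12D library 2. Mast cell, eosinophil and basophil genes did so without Cux1-low library 2 or NrasG12D library 1. Lymphoid progenitor genes did so without Cux1-low library 1, and T and NK cell genes with the replicate block. Planned tests on read counts (DESeq2, voom and other count models) were not run, because the recovered reads did not pass the unit check.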

Other observations

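All tests of the position of library 3, the tests on higher genes alone, that of the chromosome of the close neighbours, that of the summed HSP70 genes and the count over splits were chosen after the results were seen. The tests on all changed genes, on the DNA around Nras and around Hspa1a, and on the other heat shock genes were fixed beforehand.

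Among genes outside the rule for named genes, chosen after their values were seen, Gm15915, an antisense gene inside Ntn4 (chromosome 10, 93674218 to 93683322, minus strand), was at the level of 1 read in both Cux1-low libraries (0.0490 and 0.0481 normalized CPM) and at 24.0, 27.2 and 34.99 in the NrasG12D libraries. Ccnb1ip1, which encodes a ubiquitin ligase of meiotic recombination, was listed at 0 in both Cux1-low libraries and at 5.18, 8.33 and 4.80 in the NrasG12D libraries. Gnb1, a G protein subunit gene, was at 263 and 249 against 573, 558 and 594, with library 3 among the others.

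NrasG12D library 3 lay between the groups on the first principal component. On the second, which held 12.2% of the variance, it lay at -22.4, and the other libraries at -1.73 to 10.3. Its Pearson correlation over genes was 0.976 with each Cux1-low library, against 0.974 and 0.965 with NrasG12D libraries 1 and 2. A mixture of Cux1-low RNA with RNA like that of libraries 1 and 2 would give 1 relative position for higher and lower genes. Over genes stable within groups, the median was 0.253 for 169 higher genes (interquartile range 0.0768 to 0.383) and 0.580 for 588 lower genes (0.405 to 0.745). These medians speak only against that kind of mixture, and a mixture of Cux1-low RNA with an NrasG12D sample unlike libraries 1 and 2 stays open. The test on medians replaced a first criterion, a limit of 10% of higher genes above 0.8 together with 10% below 0.2. That criterion found 9.47% and 43.2%, did not count against a mixture and had been read as going with one. A Cux1-low library under the wrong label is argued against by 115 of 757 such genes (15.2%) with a relative position above 0.8. A single lower share of all differentiating cells in library 3 would give every cell type the same position. Over members higher in libraries 1 and 2, the median was 0.236 for 9 erythroid genes (lowest 0.142, highest 0.285) and 0.00328 for 8 B cell genes (lowest -0.0747, highest 0.0338). The medians of the lymphoid progenitor (-0.0370), monocyte (0.0130) and T and NK cell (0.0413) lists also lay near the Cux1-low level. A permutation of genes over 5 cell type lists gave p = 0.0009 (Kruskal-Wallis statistic). It treated genes as independent, although members of a list move together (estimated correlation 0.909 for erythroid and 0.989 for B cell genes). That p therefore does not decide on such a share. A first test set 64 cell type genes (0.371) against 9 interferon genes (0.858, permutation p = 0.00091, 1-sided). That first test had gone with a single lower share. It was dropped, because all 9 interferon genes were lower and positions depended on the direction. Over lower members, the medians were 0.572 for 16 HSC markers, 1.01 for 4 mast cell, eosinophil and basophil genes and 1.10 for 5 dendritic cell genes. Fewer cells of single types and a biological difference between animals were not tested.

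Changed genes lay close together in the genome in part: of the 128, 25.8% had another changed gene of a different family within 1 Mb, against a median of 17.97% and a 95th percentile of 26.6% in 10000 random sets matched on expression (1-sided permutation p = 0.0719), and 25.8% also with families kept (permutation p = 0.0922, median 18.8%). A family was taken as symbols with the same first 3 letters, so related genes with unlike symbols counted as different families. The criterion fixed beforehand took a p of 0.05 or more as evidence against carried segments, but that bound took a missed threshold for absence while the share lay near the 95th percentile, so for the 128 genes carried segments cannot be told apart from chance or from shared regulation. In the 29 higher genes alone the share was 37.9% against a random median of 6.90% (permutation p = 0.0001, the smallest that 10000 sets can give). These include Gm15915, which overlaps Ntn4, and Hspa1a, a near-identical copy of Hspa1b, and without these 2 the share was 33.3% of 27 genes (permutation p = 0.0001). In the 99 lower genes it was 12.1% against 14.1% (permutation p = 0.727). Lower genes above 1 normalized CPM only in the Cux1-low libraries were not listed, so the shares of higher and lower genes are not fully comparable. Segments of another strain's DNA are a candidate explanation for the higher genes, which include Tnfrsf14, Gnb1 and Samd11 on chromosome 4 and Hebp1 and Emp1 on chromosome 6, but shared regulation of neighbours was not excluded there. Samd11, like Gnb1, is outside the rule for named genes and was chosen after its values were seen. DNA flanking Nras does not account for the close neighbours, since 0 of the 33 changed genes that have one lie on chromosome 3. For the changed genes as a whole it cannot be told apart from chance, because 0 of 148 genes (0%) within 10 Mb of Nras changed, against 1.15% elsewhere (Fisher's exact p = 0.419, 2-sided), and DNA further away was not tested. The criterion fixed beforehand took any share at or below that elsewhere as evidence against it, but with so few changed genes expected in 148 a share of 0% is within chance, so that label was changed after the result was seen.

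Hspa1a and Hspa1b rose together. Reads moving between the copies are argued against by their sum, which rose 29.2-fold. Heat or handling stress of the sorted cells may contribute and cannot be told apart here, because 16 other heat shock genes had a median log2 fold change of 0.41 with 13 positive, and camera p = 5.29e-05 with the preset correlation, but p = 0.0660 with an estimated correlation, on which the test had been fixed, and 1 past the threshold. DNA of another strain around them stays open too, with 3 of 118 genes within 2 Mb changed, Hspa1a and Hspa1b left out (2.54% against 1.10%, Fisher's exact p = 0.145, 2-sided). Of these 3, Tnf was higher and H2-Aa and H2-T10 lower, and H2-T10 is outside the rule for named genes and was chosen after its values were seen. An effect of the NrasG12D allele was not tested separately.

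Of the 10 splits of the 5 libraries into 2 and 3, 2 gave at least 128 changed genes, the real one included, and the highest other gave 2643, with NrasG12D libraries 1 and 2 against the rest. With 10 splits the share cannot fall under 0.05, and the larger count points to a structure of the samples.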
